A study of Sus scrofa with 20 samples.

How the data were processed

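Skin was biopsied with a 4 mm punch at 4 sites of 5 wild-type female Yorkshire pigs and kept in RNAlater, per the labels' protocols. RNA was extracted with a fibrous tissue kit and made into TruSeq stranded mRNA libraries, per the same protocols, giving 20 libraries. The deposited table holds estimated counts per Ensembl gene for each library, made with Salmon per the submitters' processing notes. Its version, the genome build and the annotation release are not given in the sources used here. Of the values 42.2% were not whole (tolerance 0.000000001), and they were rounded to whole numbers before testing. The table has 19280 gene identifiers, of which 14821 matched a symbol in the supplied gene name tables and 4459 did not, and 1511 had no count in any library. With no build named, no coordinates are given.

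Sites were taken from the labels (volar, flank, dorsal, snout; 5 libraries each) and no library was moved. Library numbers in the labels form 2 separate ranges, here called the first set (12 libraries of the pigs aged 4, 7 and 8 months) and the second set (8 libraries of the pigs aged 5 and 6 months). Pigs are named by age in months. Totals ran from 34077861 to 66906489 counts and TMM factors from 0.569 to 1.291. No pair of libraries was a copy (highest Pearson r 0.964). The 20 most abundant genes held on average 35.7%, 22.8%, 16.5% and 19.4% of the counts in volar, flank, dorsal and snout of the first set and 19.7%, 44%, 25.6% and 17.7% in the second. Reads carry no molecular identifiers in the deposited table, so floors cover counting error only.

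Tests were edgeR 4.0.16 quasi-likelihood F tests (robust) in R 4.3.3 on site means, with TMM scaling, filterByExpr (count minimum 10, total minimum 15) and Benjamini-Hochberg adjusted p under 0.05. The planned fit held all 20 libraries (15275 genes tested, 16 residual degrees of freedom). The 6 pairwise comparisons, the test for any site, and genes set apart in a site (passing against each of the other 3 in 1 direction) were chosen before the data were examined, as were the gene lists and the alternatives. Because the labels of the sets disagreed, the same tests were also run within the first set (15302 genes, 8 residual degrees of freedom) and within the second (15280 genes, 4 residual degrees of freedom), and a site by set interaction was fitted to all libraries. The fits within sets were planned as alternatives, and reporting them as results in their own right, with their own alternatives, was chosen after seeing the data, as was the interaction.

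The 4 sites come from the same pigs per the labels, which pairs the libraries by pig. Deviations of libraries of 1 pig from the site means had a median r of 0.22 (-0.01 to 0.43) in the first set and 0.31 (0.11 to 0.44) in the second. The planned fit had no pig term, and the fit with the pig as block called 0 genes in every pooled comparison. Blocked values are given beside a result only where they change it. Values are log2 fold changes ± standard error and CPM means over 3 pigs (first set) or 2 pigs (second set) per site. A fold against a site without a count is a lower bound, computed with 3 counts over the group. Where the lower site had 1 to 3 counts the levels are given in place of a fold.

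Genes were named by a rule set beforehand. Per comparison it took genes with a symbol, adjusted p under 0.05, a mean of at least 5 CPM in the higher site and the same direction in every pig (log2 CPM with 0.5 added). Of these it took the 10 with the largest log2 fold change in each direction for comparisons with volar, and the 8 for the others. For each list described it took up to 4 passing members with the smallest adjusted p, of which those that kept their call are shown. For each site it took the 8 genes set apart by the largest margin. KRT9, DKK1, EN1, LMX1B, PITX1, TBX4, TBX5, HOXA13, HOXD13 and HOXC10 were to be reported in any case. Over all 5 pigs the rule named 0 genes, so it was applied within each set, a change made after seeing the data. KRT1, KRT10 and KRT15 for volar and flank and some list members given for contrast were chosen after their values were seen.

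Of the 36 gene lists written beforehand, members were counted over all genes and adjusted over the list alone. Lists were tested with camera in limma 3.58.1 with a preset correlation, with an estimated correlation, and with fry. The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios and upper-quartile scaling, other count filters, a log2 fold change of at least 1, a fit of 2 sites only, the 20 most abundant genes left out, and each pig or library left out. Removing 1 pig of the second set leaves no residual degrees of freedom, so that fit was not run. The tests were checked on simulated counts with the libraries of each design. For volar minus flank, with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 69 and 94 with all libraries, 32 and 72 in the first set, and 17 and 76 in the second, with 3, 7 and 5 false calls. With no gene changed, it called 0 with all libraries, 0 in the first set and 0 to 3 in the second. The simulated spread was estimated within each site of a set, and unchanged genes had the same mean in both sets. The simulation with all libraries therefore holds no disagreement between sets, and its recovery does not describe the real pooled fit. Figures were drawn with matplotlib.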

Results

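The deposited series holds RNA-seq estimated counts from skin biopsies of 5 female Yorkshire pigs, with 4 sites sampled in each pig: the sole side of the foot (labelled volar), the flank, the upper side of the foot (labelled dorsal) and the snout. The question was which genes set the hairless, weight-bearing skin of the sole apart from haired trunk and foot skin and from the snout. The 20 libraries held 34077861 to 66906489 assigned counts, with 13441 to 15051 genes at 10 or more counts. KRT1, which encodes the type II keratin of the differentiating epidermis, was the most abundant gene, followed by COL3A1 and COL1A2, which encode fibrillar collagens of the dermis. The 20 most abundant genes held 13.9% to 45.4% of the counts of a library. By library number the pigs fall into 2 sets. The first set holds 12 libraries of the pigs aged 4, 7 and 8 months and the second set 8 libraries of the pigs aged 5 and 6 months. Site names below are those of the labels, and no library was moved to another site.

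The labels of the 2 sets disagree on which skin is which. EN1, a homeobox gene of the ventral limb ectoderm, reached 11.8 ± 2.8 CPM (mean ± SD) in the volar libraries of the first set and 17.3 ± 3.7 CPM in the flank libraries of the second. KRT1 followed it, with 202000 CPM in first-set volar and 425000 CPM in second-set flank, as did the sweat gland water channel gene AQP5 (ENSSSCG00000000211; 1350 and 4760 CPM). These CPM are TMM-scaled, so 425000 CPM is not a plain share of the counts. The sweat gland list did not go with AQP5 in the second set, with 8 members higher and 3 lower in volar than in flank. ALX1 (ENSSSCG00000036744), a regulator of facial mesenchyme, was at 18.5 CPM in first-set snout and 19.4 CPM in second-set volar. KRT24 (ENSSSCG00000017465), a keratin gene of mucosal and palmoplantar epithelium, went with it (13000 and 14600 CPM). KRT71 (ENSSSCG00000000247), a keratin of the inner root sheath of hair, stood at 0.0858 CPM in first-set volar and 10.6 CPM in second-set flank, against 3000 and 4980 CPM in dorsal. The second-set flank mean is of 0.0917 CPM in the 6-month pig and 21.1 CPM in the 5-month pig. HOXC10, a patterning gene of the lower trunk and hind limb, had no count in first-set snout or in second-set volar.

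**Figure D1:**
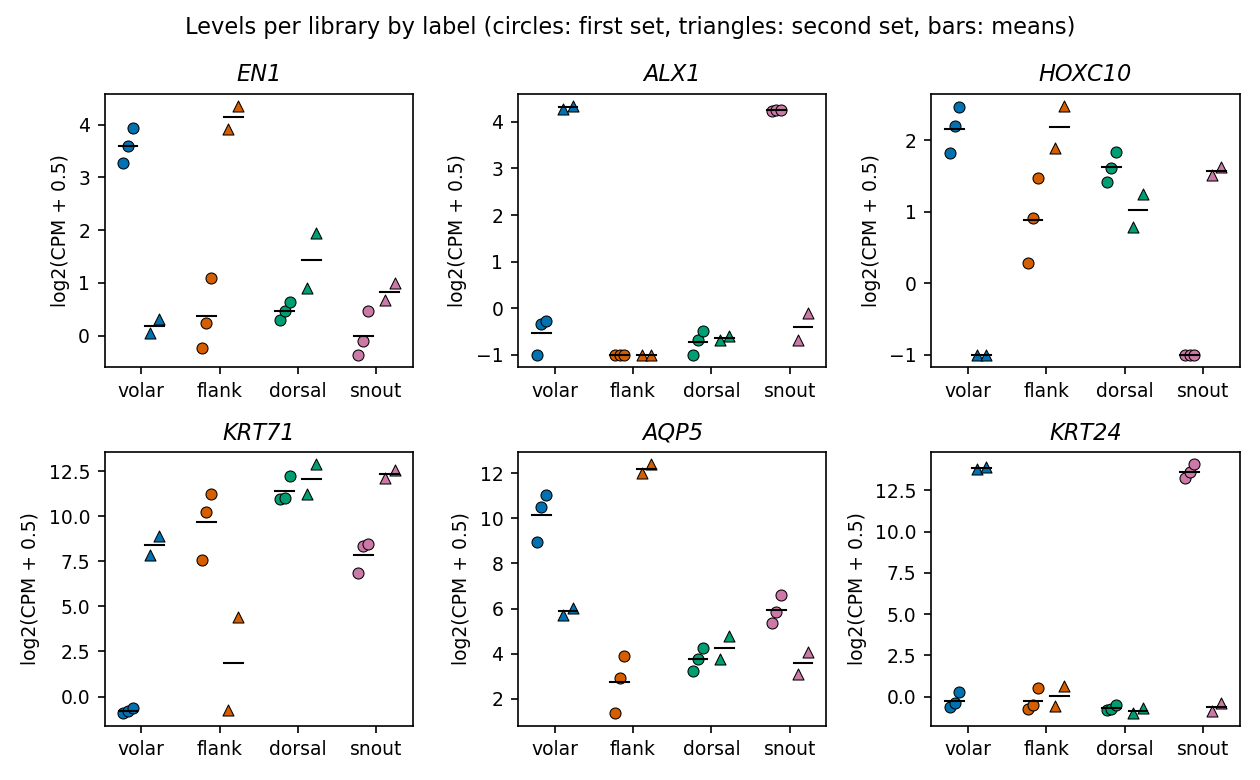
Levels of EN1, ALX1, HOXC10, KRT71, AQP5 and KRT24 in each library by label, with circles for the first set and triangles for the second. EN1 and AQP5 peak under volar in the first set and under flank in the second, and ALX1 and KRT24 under snout in the first and volar in the second.

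The same split ran through the 2000 most variable genes. Correlations and components here are over these genes, which are not independent replicates. Libraries with the same label had a median Pearson r of 0.935 (0.798 to 0.964) within the first set and 0.953 (0.934 to 0.957) within the second, but 0.7 (0.444 to 0.921) between sets, where libraries with different labels had 0.677. Principal component 1 held 52.6% of the variance and component 2 held 21.9%. For the matches, each gene was centred on the mean of its set, so these r values are not on the scale of those above. Each second-set library was closest to a first-set site of another name. The flank libraries matched first-set volar (r = 0.87 and 0.87), the volar libraries matched snout (0.83 and 0.77), the dorsal libraries matched flank (0.81 and 0.84) and the snout libraries matched dorsal (0.86 and 0.82). The second-set volar libraries and the 7-month snout library carry skeletal muscle genes, and the match of volar to snout was not computed without these genes. In the first set, 11 of 12 libraries were closest to the other libraries of their own label; the flank library of the 7-month pig was closest to dorsal (0.68 against 0.66).

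**Figure D2:**
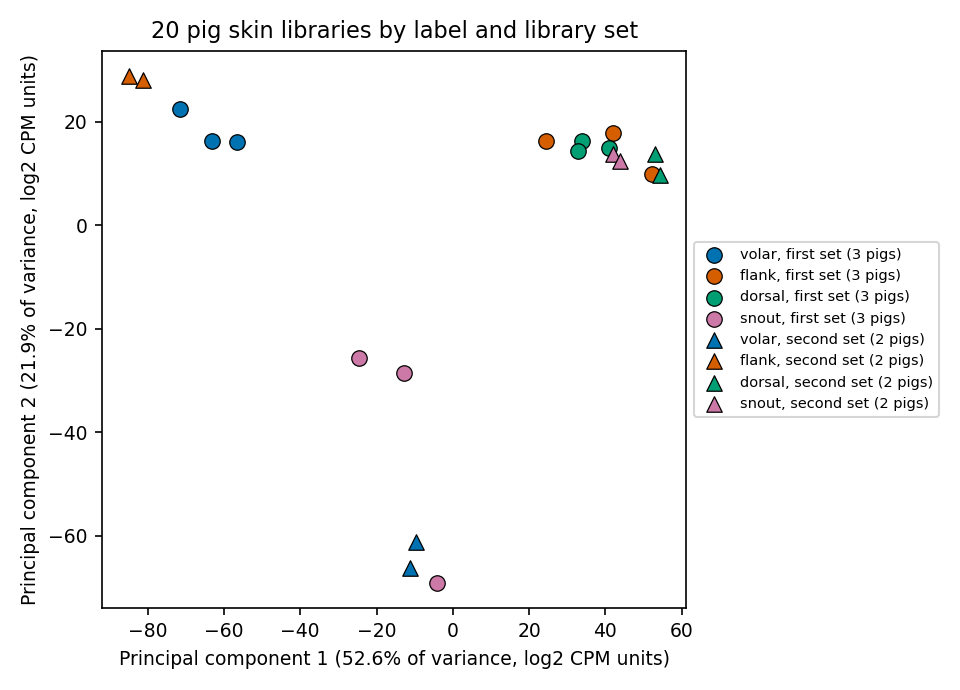
Libraries on principal components 1 (52.6% of variance) and 2 (21.9%), coloured by label, with circles for the first set and triangles for the second. First-set volar libraries lie nearest to second-set flank libraries. The second-set volar libraries (-66.2 and -61.1 on component 2) lie beside the 7-month snout library of the first set (-69), and these 3 carry skeletal muscle genes. The 4- and 8-month snout libraries lie apart from them (-25.6 and -28.6).

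**Figure D3:**
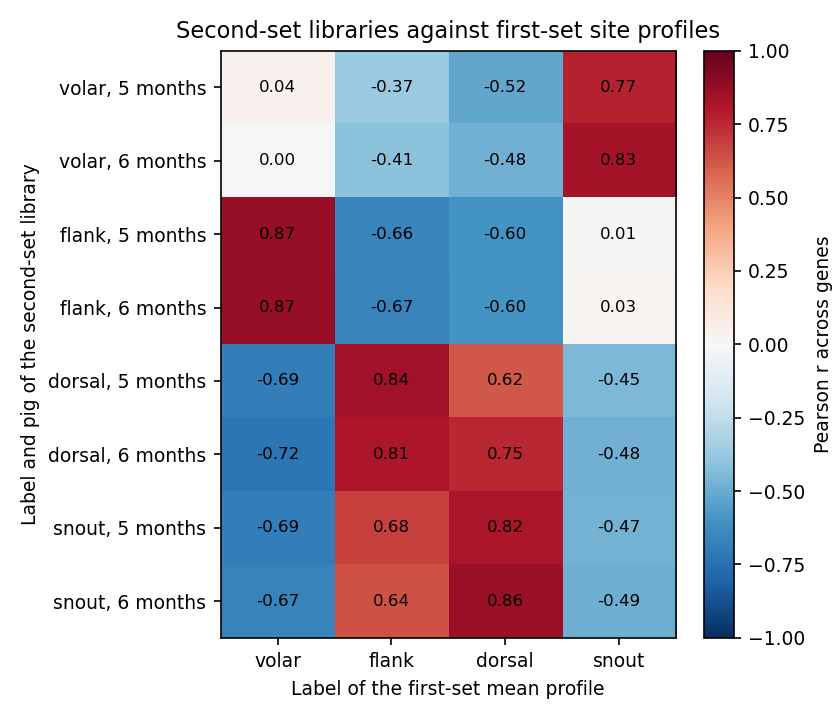
Pearson r across the 2000 most variable genes of each second-set library with the mean site profiles of the first set, each centred on its own set's mean. The highest value in every line lies under a different label, from 0.77 to 0.87.

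With all 20 libraries in 1 fit, none of the planned comparisons called a gene in edgeR. Volar and flank gave 0 genes (1805 with unadjusted p under 0.05, lowest adjusted p = 0.11), and EN1 did not differ (log2 fold change -0.02 ± 0.98, adjusted p = 0.997). Volar and dorsal gave 0 (3877, lowest 0.0877), volar and snout 0 (992, 0.738), snout and flank 0 (1782, 0.148), snout and dorsal 0 (702, 0.354), and dorsal and flank 0 (1791, 0.322). The test for any site gave 0 (2576, 0.187), and no gene was set apart in a single site. HOXC10 gave 1.30 ± 1.40 (adjusted p = 0.825) for volar minus snout, TBX5, which marks the forelimb, -0.35 ± 1.41 (0.967), LMX1B, which specifies the dorsal limb, -1.06 ± 0.64 (0.742), and TBX4, which marks the hind limb, 0.56 ± 0.68 (0.848). DKK1, a WNT inhibitor of palmoplantar fibroblasts, gave 1.13 ± 0.53 (0.415) for volar minus flank. limma-voom also called 0 genes in each. DESeq2 called 319, 1631, 47, 304, 70 and 186 genes in the 6 comparisons in the same order and 781 for any site. It set 19 genes apart in volar, 10 in flank, 7 in dorsal and 1 in snout. With only the libraries of the 2 sites in the fit, edgeR called 2595 genes between volar and dorsal (1474 higher, 1121 lower) and 1 between dorsal and flank, and 0 in the other 4. Second-set volar and dorsal matched first-set snout and flank, so the 2595 genes are not read as a difference of sole and upper foot. Leaving out single libraries gave at most 30 genes for any site (without the 7-month snout library). It gave at most 5 for volar and flank (without the 7-month volar library), 3 for volar and dorsal (without the 5-month flank library) and 2 for snout and flank (without the 5-month dorsal library).

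In the pooled fit, hair genes gave the strongest list result, with no member called over all genes. For volar minus snout the hair shaft and inner root sheath list was lower (camera adjusted p = 2.43e-17, or 0.374 with an estimated correlation, 1 of 22 members higher and 17 lower when adjusted over the list alone). For volar minus dorsal it was lower too (1.29e-14, or 0.607 with an estimated correlation, 1 higher and 21 lower over the list alone). Cornified envelope genes were lower in dorsal than in flank (1.86e-05, or 0.45 with an estimated correlation, 0 higher and 19 lower over the list alone), a direction that the second set gave (8560 against 79800 CPM summed). In the first set camera put the list higher in dorsal (adjusted p = 1.74e-05, or 0.439 with an estimated correlation), with no member called. Its summed level there was 12600 ± 1200 against 11300 ± 3600 CPM (mean ± SD), a difference within the spread of the flank libraries. Of the 36 lists, camera called 9 for volar and flank, 13 for volar and dorsal, 17 for volar and snout, 20 for snout and flank, 13 for snout and dorsal and 20 for dorsal and flank, and 0 in each with an estimated correlation. Because the sets differ, the 6 comparisons are described within each set below.

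**Figure D4:**
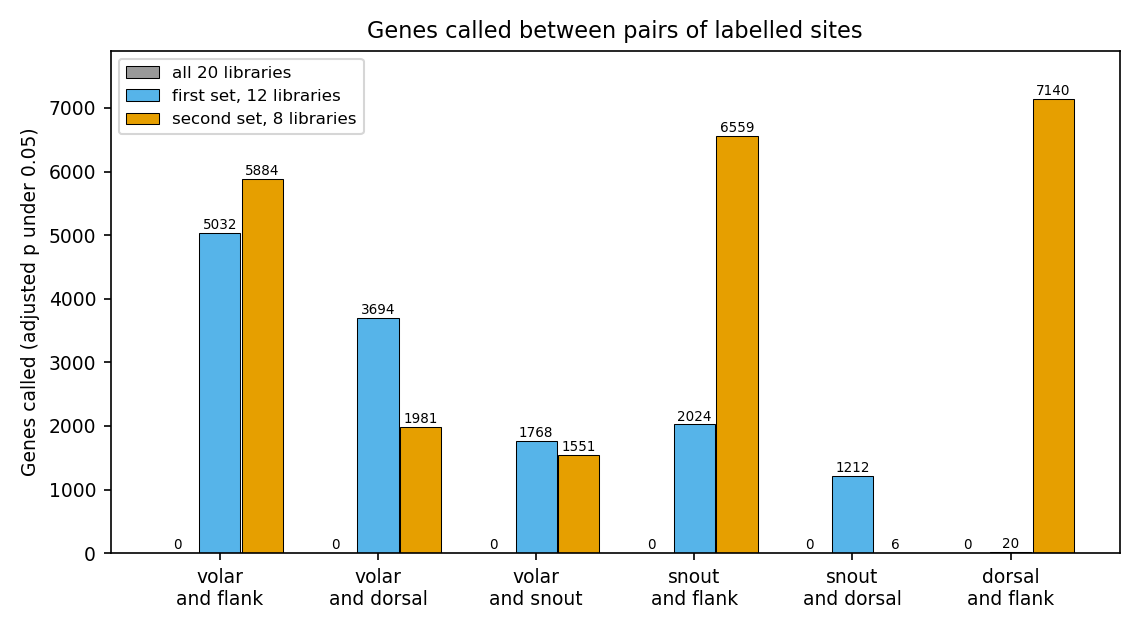
Genes called between pairs of labelled sites in the fit of all 20 libraries, in the first set and in the second set. The pooled fit calls 0 in each pair while the sets call up to 5032 and 7140.

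In the first set, volar against flank was a contrast of keratin and cornified envelope genes with hair genes. KRT78, a keratin of differentiating keratinocytes, was higher in volar (log2 fold change 9.99 ± 0.66, adjusted p = 7.91e-06; 1950 against 1.91 CPM). The calcium-binding alarmin genes S100A12 (9.92 ± 0.84, 3.33e-05) and S100A8 (10.82 ± 1.07, 7.86e-05), the keratin gene KRT3 (11.99 ± 1.42, 0.000205; 12400 against 3.02 CPM) and the protease inhibitor gene A2ML1 (9.61 ± 0.68, 1.23e-05) rose with it. So did AQP5 (7.43 ± 0.86, 0.000182), the tendon matrix genes COMP (8.70 ± 0.91, 0.000108) and THBS4 (7.56 ± 0.63, 2.87e-05), and the limb bud factor gene SP8 (at least 364-fold, 0.000167). KRT1 (4.37 ± 0.27, 7.11e-06), its partner KRT10 (4.53 ± 0.29) and EN1 (3.72 ± 0.57, 0.000784) were higher as well, while the basal keratin gene KRT15 was lower (-5.41 ± 0.50). Hair genes were lower in volar, among them KRT71 (-13.84 ± 1.31, 6.31e-05; 0.0858 against 1270 CPM), TCHHL1 of the inner root sheath (at least 2490-fold), KRT39 of the hair shaft (at least 1020-fold) and KRTAP27-1 (at least 779-fold). The sulfotransferase gene SULT1C4 was at least 862-fold lower.

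By lists, 19 of 24 cornified envelope genes rose and 2 fell from flank to volar in the first set (camera adjusted p = 1.43e-08, or 0.493 with an estimated correlation, 19 and 3 over the list alone), among them SERPINB12 (4.92 ± 0.33), TGM5 (3.59 ± 0.33) and CDSN (2.40 ± 0.23). Hair shaft and inner root sheath genes went the other way, with 1 higher and 19 lower of 22 (1.52e-10, or 0.493 with an estimated correlation, 1 and 20 alone), such as KRT35 (-11.21 ± 1.31) and KRT85 (-11.44 ± 1.41). Of 19 glycolysis genes 10 rose and 0 fell (0.000173, or 0.493 with an estimated correlation, 10 and 0 alone), among them HK1 (1.48 ± 0.15) and PKM (1.01 ± 0.12). Of 15 adipocyte genes 0 rose and 11 fell (0.000173, or 0.555 with an estimated correlation, 0 and 14 alone), including LPL (-4.92 ± 0.80). Of 33 desmosome and junction genes 16 rose and 3 fell (0.000119, or 0.493 with an estimated correlation, 17 and 3 alone), with DSP at 2.03 ± 0.19 and PERP at 1.76 ± 0.19. HOX paralogs 1 to 8 were the 1 list that held with an estimated correlation, with 0 higher and 14 lower of 19 (2.53e-07, or 0.0105 with an estimated correlation, 0 and 15 alone), such as HOXC6 (-2.65 ± 0.38).

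The first set called 5032 genes between volar and flank (2588 higher, 2444 lower), more than in any other pair of that set. Upper-quartile scaling turned the split to 2096 higher and 2952 lower, so the share of genes higher in volar depends on the scaling. Of the 20 genes named, 14 kept their call under every alternative and removal. CCND2 lost it in 6 single-library removals (highest adjusted p = 0.109) and ELOVL6 in 4 (0.231). CPHL1 lost it in limma-voom (0.119), and TDO2, KRT32 and KRT73 reached 0.0828, 0.085 and 0.132.

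The same pair of names in the second set gave a contrast of muscle and hair genes against cornified envelope genes. Sarcomere genes were higher in volar, among them MYOT (at least 2040-fold, adjusted p = 0.000415), MYOZ1 (at least 1430-fold, 0.00185), LMOD2 (at least 1410-fold, 0.000344) and XIRP2 (1420 against 0.0458 CPM), with MYL11 at 649 against 0.0404 CPM. KRT24 was higher too (14.62 ± 1.03, 0.000228; 14600 against 0.614 CPM), as was the hair keratin gene KRT85 (at least 955-fold). SP8 was at least 383-fold lower, and AQP5 (-6.35 ± 0.53, 0.000392), the ammonium transporter gene RHCG (-6.62 ± 0.62), the water channel gene AQP2 (-7.61 ± 0.80), KRT1 (-6.51 ± 0.37, 0.000137) and EN1 (-4.73 ± 0.50, 0.000846) fell. The protease inhibitor gene SPINK9 (-5.61 ± 0.39) and the arginase gene ARG1 (-6.26 ± 1.10) fell with them. Of the 20 skeletal muscle genes 20 rose (camera adjusted p = 2.93e-15, or 0.337 with an estimated correlation, 20 over the list alone), such as MYBPC1 (8.75 ± 0.26) and CKM (8.30 ± 0.36). Cornified envelope genes had 2 higher and 20 lower of 24 (5.97e-09, or 0.341 with an estimated correlation, 2 and 20 alone), with KLK5 at -4.57 ± 0.31 and TGM5 at -2.19 ± 0.16. Hair shaft and inner root sheath genes had 19 higher and 2 lower of 22 (1.96e-07, or 0.341 with an estimated correlation, 19 and 3 alone), with KRT82 at 5.94 ± 0.39.

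The second set called 5884 genes between volar and flank (3198 higher, 2686 lower) and 3554 without the volar library of the 5-month pig. Of its 20 named genes 18 kept their call; CBR2 lost it in 3 single-library removals (highest adjusted p = 0.0665) and HOXA9 in 2 (0.148). The direction was turned around between sets. Of 2937 genes called in both, 2836 had opposite signs, and the log2 fold changes of the sets had r = -0.58 over 15087 genes.

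Volar against dorsal is the within-foot contrast of the first set, where several genes named against flank came up again. KRT3 (log2 fold change 9.53 ± 1.30, adjusted p = 0.000653), S100A8 (9.23 ± 1.01, 0.000199), S100A12 (8.44 ± 0.79, 7.70e-05), A2ML1 (8.55 ± 0.65, 2.48e-05) and KRT78 (7.53 ± 0.59, 2.70e-05) were higher in volar. AQP5 (6.66 ± 0.83, 0.000398), ARG1 (6.03 ± 0.63), THBS4 (5.41 ± 0.57), the keratinocyte factor gene ZBED2 (5.72 ± 0.43), KRT1 (3.89 ± 0.26) and EN1 (3.73 ± 0.57, 0.00107) rose with them. Hair genes fell: KRT71 (-15.07 ± 1.35, 7.10e-05; 0.0858 against 3000 CPM), TCHHL1 (at least 3070-fold), KRTAP27-1 (at least 1990-fold), KRT39 (at least 1950-fold) and KRTAP11-1 (-13.18 ± 1.61). LGR5, which marks hair follicle stem cells, had no count in volar and 22 CPM in dorsal (at least 952-fold, 2.31e-05). Of the 22 hair shaft and inner root sheath genes 1 rose and 21 fell (camera adjusted p = 5.19e-17, or 0.329 with an estimated correlation, 1 and 21 over the list alone), with CRYM the gene that rose (2.77 ± 0.28). Cornified envelope genes had 19 higher and 4 lower of 24 (1.84e-07, or 0.329 with an estimated correlation, 20 and 4 alone), such as CNFN (3.97 ± 0.42) and SERPINB12 (4.34 ± 0.32). Hair follicle regulators had 2 higher and 10 lower of 18 (0.00369, or 0.329 with an estimated correlation, 4 and 11 alone), with SOX9 (-2.83 ± 0.39) and PTCH1 (-0.75 ± 0.12) lower. Glycolysis genes had 9 higher and 0 lower of 19 (4.03e-05, or 0.329 with an estimated correlation, 10 and 0 alone), with ENO1 at 0.94 ± 0.15.

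Second-set volar was marked against dorsal by muscle genes. TNNT3, which encodes fast skeletal troponin T, was higher (at least 17700-fold, adjusted p = 0.000246), with MYOT (at least 3850-fold), MYOZ1 (at least 2700-fold), CSRP3 (at least 2400-fold) and MYL11 (12.86 ± 0.44, 4.42e-05). KRT24 (17.57 ± 1.15, 0.000347) and the airway protease gene TMPRSS11D (at least 4340-fold) rose as well. Trunk patterning genes fell, HOXC9 at least 210-fold and HOXC8 from 14.7 CPM in dorsal to 0.00742 CPM in volar, with KRT2, a keratin of the upper epidermis (-8.46 ± 0.59), KRT77 of the sweat duct (-7.52 ± 0.68) and the chitinase gene CHIA (-8.95 ± 0.93). The skeletal muscle list had 20 of 20 higher (camera adjusted p = 3.21e-27, or 0.107 with an estimated correlation, 20 over the list alone). Lower in volar were HOX paralogs 1 to 8, with 0 higher and 15 lower of 18 (2.47e-14, or 0.0976 with an estimated correlation, 0 and 17 alone), with HOXB2 at -5.20 ± 0.53. Craniofacial genes had 12 higher and 0 lower of 26 (1.64e-07, or 0.0976 with an estimated correlation, 17 and 0 alone), with MSX1 at 4.70 ± 0.29 and ALX1 at 7.10 ± 0.59. Hair shaft and inner root sheath genes had 0 higher and 18 lower of 22 (6.51e-13, or 0.281 with an estimated correlation, 1 and 19 alone), with KRT82 at -3.88 ± 0.25.

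Counts for volar and dorsal were 3694 in the first set (2142 higher, 1552 lower) and 2360 without the dorsal library of the 7-month pig. Upper-quartile scaling turned the split to 1593 higher and 1981 lower, with a median shift of -0.11, so the share of genes higher in volar depends on the scaling. The second set called 1981 genes (1163 higher, 818 lower), and 693 or 820 without the volar library of the 6-month or 5-month pig, 1316 without the 5-month snout library and 1235 without the 5-month dorsal library. Of the named genes 15 of 20 kept their call in the first set and 16 of 20 in the second. Those that lost it were CCND2 (6 single-library removals, highest adjusted p = 0.117), CPHL1 (0.129), KRT73 (0.0738), KRT32 (0.0716) and TDO2 (0.0964) in the first. In the second they were PGAM2 (0.053), TDO2 (4 removals, 0.0979), CPHL1 (4 removals, 0.231) and SULT1C4 (0.0895). This was the pair with the most shared direction: 51 of 1024 genes called in both sets had opposite signs (r = 0.46). By the matches above, second-set volar and dorsal were closest to first-set snout and flank. The shared direction is therefore not read as the same site difference seen in both sets.

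Against snout, first-set volar had more RHCG and KRT1 and less KRT24. RHCG (log2 fold change 6.18 ± 0.32, adjusted p = 4.44e-06; 511 against 7.02 CPM), KRT1 (5.67 ± 0.29, 4.44e-06), ARG1 (4.57 ± 0.58), the receptor gene EPHA8 (5.76 ± 0.40), the collagenase gene MMP13 (4.56 ± 0.44), S100A12 (4.56 ± 0.66) and SP8 (7.83 ± 0.84) were higher. KRT24 fell (-15.11 ± 1.06, 2.61e-05; 0.376 against 13000 CPM), with TMPRSS11D (-11.87 ± 0.57, 4.44e-06), the cornulin gene CRNN (-7.06 ± 0.54), KRT71 (-11.57 ± 1.24) and the transglutaminase gene TGM7 (-10.94 ± 0.89). Position genes separated limb from face. HOX paralogs 1 to 8 had 13 higher and 0 lower of 19 (camera adjusted p = 6.59e-12, or 0.00182 with an estimated correlation, 14 and 1 over the list alone), and HOX paralogs 9 to 13 had 8 higher and 0 lower of 12 (1.49e-12, or 0.0164 with an estimated correlation, 10 and 0 alone). HOXC11 (4.35 CPM), HOXC10 (4.06 CPM) and HOXC9 (1.62 CPM) had no count in snout. TBX5 was higher in volar (3.48 against 0.00571 CPM, adjusted p = 8.33e-05), and LMX1B (-3.84 ± 0.30, 5.25e-05) and MSX1 (-3.07 ± 0.28) were higher in snout. Craniofacial genes had 2 higher and 8 lower of 25 (0.00272, or 0.33 with an estimated correlation, 3 and 10 alone). Hair shaft and inner root sheath genes had 1 higher and 18 lower of 22 (2.33e-14, or 0.238 with an estimated correlation, 1 and 19 alone), and cornified envelope genes 9 higher and 2 lower of 24 (0.000127, or 0.443 with an estimated correlation, 13 and 2 alone).

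Position genes of the second set ran the other way for the same names. TBX5 (0.00742 against 6.66 CPM) and HOXA11 (0.0223 against 5.48 CPM) were lower in volar than in snout, and so were KRT2 (log2 fold change -8.93 ± 0.60, adjusted p = 0.000395) and KRT77 (-7.46 ± 0.68). KRT24 (16.36 ± 1.08, 0.000377), MYOT (at least 4360-fold), MYOZ1 (at least 3060-fold), CSRP3 (at least 2710-fold) and TNNT3 (557 against 0.0239 CPM) were higher. HOX paralogs 9 to 13 had 0 higher and 10 lower of 11 (camera adjusted p = 7.33e-12, or 0.0604 with an estimated correlation, 10 lower over the list alone), with HOXD11 at -2.96 ± 0.33. Craniofacial genes had 9 higher and 2 lower of 26 (0.00115, or 0.244 with an estimated correlation, 12 and 2 alone), with MSX1 (3.35 ± 0.27) and PAX3 (5.88 ± 0.65). Skeletal muscle genes had 20 of 20 higher (4.38e-31, or 0.114 with an estimated correlation, 20 alone).

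Volar and snout differed in 1768 genes in the first set (873 higher, 895 lower), and in 1033 or 1025 without the snout or volar library of the 7-month pig. The second set called 1551 (991 higher, 560 lower) and 464 to 621 when any of its 4 volar or snout libraries was left out. Muscle genes in the first set rest on 1 snout library: ACTA1 (-10.82 ± 2.86) lost its call in 9 single-library removals (adjusted p = 0.42 without the 7-month snout library, and 0.125 with the pig as block), and MYL11 in 10 (0.96). Of the named genes 11 of 20 in the first set and 14 of 20 in the second kept their call. The others in the first set were HOXA9 (0.118), KRT2 (0.0905), S100A8 (0.062), SAL1 (0.465), PHEROC (3 removals, 0.663), CLDN17 (0.0797) and DGAT2L6 (0.144), with the highest adjusted p of any alternative. In the second they were PGAM2 (0.0581), TDO2 (0.17), HOXA9 (0.192), HOXA10 (0.101), SULT1C4 (0.176) and CHIA (0.0545). Of 459 genes called in both sets 263 had opposite signs (r = -0.22).

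Snout against flank in the first set was a face against trunk contrast. KRT24 (log2 fold change 15.02 ± 1.05, adjusted p = 2.81e-05), KRT3 (13.11 ± 1.47, 0.000423; 26800 against 3.02 CPM), TMPRSS11D (11.95 ± 0.56, 4.70e-06), the kallikrein gene KLK12 (7.66 ± 0.45) and COMP (7.84 ± 0.89) were higher in snout. HOXC8 (at least 576-fold, 5.78e-05), HOXC4 (at least 334-fold), KRT2 (-8.73 ± 1.17) and FIBCD1, a receptor gene for acetylated sugars (-9.25 ± 0.59), were lower. Here 4 lists held with an estimated correlation. HOX paralogs 1 to 8 had 0 higher and 17 lower of 19 (camera adjusted p = 3.82e-25, or 9.73e-05 with an estimated correlation, 0 and 19 over the list alone), among them HOXB2 (-7.24 ± 0.70). HOX paralogs 9 to 13 had 0 higher and 8 lower of 12 (3.46e-08, or 0.0405 with an estimated correlation, 0 and 9 alone). Craniofacial genes had 16 higher and 0 lower of 25 (4.70e-10, or 0.0405 with an estimated correlation, 18 and 0 alone), with MSX1 at 4.73 ± 0.30 and FOXF2 at 3.66 ± 0.33. Mucosal epithelium genes had 5 higher and 0 lower of 9 (7.36e-05, or 0.0321 with an estimated correlation, 5 and 0 alone), with CRNN (6.05 ± 0.51) and TMPRSS11A (7.52 ± 0.65). Tendon genes had 8 higher and 1 lower of 14 (0.000116, or 0.512 with an estimated correlation, 9 and 2 alone), with THBS4 at 6.45 ± 0.60 and MKX at 2.50 ± 0.25.

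For the second set the same names gave a contrast of hair genes with cornified envelope genes. Hair genes were higher in snout: KRT85 (at least 9650-fold, adjusted p = 0.000389), KRTAP24-1 (at least 3620-fold, 5.69e-05), TCHHL1 (at least 2410-fold), KRT39 (at least 1250-fold) and KRT32 (at least 841-fold), with the collagen gene COL6A5 (at least 1850-fold) and the zinc transporter gene SLC39A10 (at least 1020-fold). S100A8 (log2 fold change -11.02 ± 0.98, 0.000334; 3.58 against 7340 CPM), S100A12 (-10.02 ± 0.64), A2ML1 (-9.64 ± 0.64), KRT78 (-9.16 ± 0.46, 7.22e-05), KRT3 (-8.92 ± 1.5), AQP5 (-8.62 ± 0.58), ARG1 (-7.99 ± 1.22) and AQP2 (at least 304-fold lower) fell. Cornified envelope genes had 3 higher and 20 lower of 24 (camera adjusted p = 4.50e-10, or 0.369 with an estimated correlation, 3 and 20 over the list alone), such as TGM5 (-4.08 ± 0.17). Barrier lipid genes had 0 higher and 23 lower of 25 (4.50e-10, or 0.369 with an estimated correlation, 0 and 23 alone), with ABHD5 at -2.12 ± 0.13 and ELOVL4 at -2.24 ± 0.18. Hair shaft and inner root sheath genes had 19 higher and 1 lower of 22 (2.16e-10, or 0.369 with an estimated correlation, 19 and 1 alone). Adipocyte genes had 12 higher and 0 lower of 15 (4.45e-05, or 0.369 with an estimated correlation, 12 and 0 alone), including CFD (3.70 ± 0.27) and ADIPOQ (6.80 ± 0.76).

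Between snout and flank the first set called 2024 genes (1189 higher, 835 lower), and 1318 or 1263 without the snout library of the 4-month or 8-month pig. The second set called 6559 (3448 higher, 3111 lower), and 4256 or 4023 without the snout library of the 6-month or 5-month pig. Upper-quartile scaling moved the second-set split to 4163 higher and 2483 lower, with a median shift of 0.15. Kept calls were 9 of 16 and 15 of 16. Named genes that lost theirs were ALX1 (highest adjusted p = 0.0626), MYL11 (4 removals, 0.528), ANGPTL7 (3 removals, 0.129), CPHL1 (0.156), TDO2 (0.142), SULT1C4 (0.0888) and HOXA9 (0.126) in the first set and CPHL1 (0.303) in the second. Of 1389 genes called in both sets 1249 had opposite signs (r = -0.37).

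Snout against dorsal in the first set was marked by higher KRT24 and lower HOX genes. KRT24 (log2 fold change 16.72 ± 1.12, adjusted p = 3.01e-05), KRT3 (10.65 ± 1.35, 0.00128), TMPRSS11D (10.23 ± 0.49, 6.83e-06) and KLK12 (7.28 ± 0.44, 2.45e-05) were higher in snout, with CRNN (4.90 ± 0.48), LMX1B (2.30 ± 0.28, 0.000932) and the tendon factor gene MKX (2.25 ± 0.25). TBX5 (0.00571 against 5.56 CPM), KRT2 (-9.20 ± 1.19) and FIBCD1 (-7.95 ± 0.58) were lower. For HOX paralogs 1 to 8, 0 were higher and 14 lower of 19 (camera adjusted p = 1.29e-21, or 0.000173 with an estimated correlation, 0 and 16 over the list alone), such as HOXC5 (-6.40 ± 0.67). HOX paralogs 9 to 13 had 0 higher and 10 lower of 12 (2.68e-18, or 0.00467 with an estimated correlation, 0 and 11 alone), with HOXC10 (2.61 CPM) and HOXC9 (2.04 CPM) present in dorsal and without a count in snout. Craniofacial genes had 12 higher and 1 lower of 25 (1.58e-05, or 0.211 with an estimated correlation, 12 and 2 alone), with MSX1 at 3.79 ± 0.29 and the lone fall in PAX9 (-4.82 ± 0.62). Hair follicle regulators had 0 higher and 5 lower of 18 (0.00044, or 0.206 with an estimated correlation, 0 and 6 alone), with GATA3 at -3.03 ± 0.41. TBX4 was lower in snout (-2.50; adjusted p = 0.0207) and lost its call without the 4-, 8- or 7-month snout library (0.0642, 0.053 and 0.0745) or the 4- or 7-month dorsal library (0.0763 and 0.0635).

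The second set named 3 genes for this pair, in a design that recovered 17 of 100 genes changed 2-fold in simulated data for volar and flank. CILP, a cartilage matrix gene (log2 fold change 1.84 ± 0.15, adjusted p = 0.0402), and LYPD2 (1.54 ± 0.15, 0.0402) were higher in snout and MGST1, a glutathione transferase gene (-1.89 ± 0.17, 0.0402), was lower. None kept its call under every single-library removal (8, 8 and 7 removals; highest adjusted p 0.136, 0.162 and 0.277). HOX paralogs 9 to 13 had 0 of 11 called over all genes and 6 higher and 1 lower over the list alone (camera adjusted p = 2.11e-07, or 0.136 with an estimated correlation). HOX paralogs 1 to 8 had 0 of 18 called, and 0 higher and 5 lower over the list alone (1.13e-05, or 0.271 with an estimated correlation; 51.8 ± 8.3 against 97 ± 3.9 CPM summed).

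Totals for snout and dorsal were 1212 genes in the first set (765 higher, 447 lower) and 6 in the second (5 higher, 1 lower; 1223 with unadjusted p under 0.05). DESeq2 called 2045 and 272. With the pig as block the second set gave 34 genes (9 higher, 25 lower). Removing a snout library of the 4-, 8- or 7-month pig left 771, 784 or 790 genes in the first set, and removing a dorsal library left 612, 600 or 597. Upper-quartile scaling moved the first-set split to 599 higher and 530 lower. In the second set 0 genes were left without the 6-month snout library, the 6-month flank library or the 5-month flank library, and 1 without either volar library or the 5-month snout library. First-set genes that kept their call were 7 of 16. MYL11, ACTA1 and CKM lost theirs in 10 single-library removals each (highest adjusted p = 0.581, 0.623 and 0.5), and with the pig as block ACTA1 was at 0.222 and CKM at 0.189. ALX1 (0.116), CPHL1 (0.182), TDO2 (4 removals, 0.188; 0.0563 with the block), HOXA9 (0.129), HOXA10 (0.105) and SULT1C4 (0.126) lost theirs too.

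Dorsal and flank, both haired, had few called genes in the first set. DIO2, which activates thyroid hormone (log2 fold change 2.31 ± 0.33, adjusted p = 0.0266), RHCG (1.87 ± 0.27, 0.0266), the growth factor gene PTN (1.15 ± 0.13, 0.0143) and the cadherin gene CELSR2 (0.85 ± 0.13, 0.0409) were higher in dorsal. KCNE4 (-2.58 ± 0.34, 0.0213), BMP3 (-2.40 ± 0.29, 0.0145), HAPLN4 (-2.35 ± 0.36, 0.0409), the kinase gene FGR (-2.31 ± 0.34, 0.0326), AFF2 (-1.91 ± 0.30, 0.0409), the collagen crosslinking gene LOXL4 (-1.72 ± 0.23, 0.0213) and QPCT (-1.69 ± 0.21, 0.0169) were lower. None of these 11 kept its call under every alternative: each lost it without the 8-month pig (adjusted p 0.325 to 0.562) and in 2 to 10 single-library removals, and DIO2, HAPLN4 and AFF2 with the pig as block (0.0505 each). HOX genes carried the trunk to foot axis as groups. HOX paralogs 1 to 8 were lower in dorsal with 0 of 19 called over all genes and 9 lower over the list alone (camera adjusted p = 1.17e-15, or 0.000579 with an estimated correlation). HOX paralogs 9 to 13 were higher (5.73e-08, or 0.044 with an estimated correlation, 1 of 12 called, 4 higher and 1 lower alone). Mucosal epithelium genes were higher as well (1.67e-08, or 0.00391 with an estimated correlation, 2 of 9 called, 5 alone).

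The second-set pair with these names was the most different of all. KRT85 (at least 8730-fold, adjusted p = 0.000327), TCHHL1 (at least 3270-fold), KRTAP24-1 (at least 2230-fold), KRT39 (at least 929-fold), COL6A5 (at least 881-fold) and SLC39A10 (at least 808-fold) were higher in dorsal. S100A8 (log2 fold change -10.46 ± 0.96, 0.000294), A2ML1 (-10.28 ± 0.66), S100A12 (-10.13 ± 0.64), KRT78 (-10.09 ± 0.48, 5.56e-05), KRT3 (-9.75 ± 1.55), the cytokine receptor gene IL17RB (at least 366-fold lower), AQP2 (0.013 against 8.49 CPM), SP8 (0.0261 against 11 CPM) and EN1 (-2.85 ± 0.45, 0.00242) fell. Cornified envelope genes had 3 higher and 20 lower of 24 (camera adjusted p = 7.76e-10, or 0.384 with an estimated correlation, 3 and 20 over the list alone), with TGM5 at -4.58 ± 0.18. Hair shaft and inner root sheath genes had 19 higher and 2 lower of 22 (2.61e-09, or 0.384 with an estimated correlation, 19 and 2 alone), with KRT82 at 9.82 ± 0.38. Elastic fibre and small matrix genes had 30 higher and 0 lower of 39 (4.38e-09, or 0.384 with an estimated correlation, 31 and 0 alone), such as DCN (3.96 ± 0.26) and OGN (5.02 ± 0.35). Adipocyte genes had 13 higher and 0 lower of 15 (4.95e-06, or 0.384 with an estimated correlation, 14 and 0 alone), with LIPE at 5.70 ± 0.57. HOX paralogs 1 to 8 had 12 higher and 0 lower of 18 (0.000878, or 0.384 with an estimated correlation, 13 and 0 alone), with HOXC8 at 4.04 ± 0.36.

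Calls between dorsal and flank numbered 20 in the first set (12 higher, 8 lower; 1380 with unadjusted p under 0.05) and 7140 in the second (3865 higher, 3275 lower). The first-set count was 32 with the pig as block, 350 in DESeq2 and 48 in limma-voom. It ran from 1 without the 8-month dorsal library (2 without the 4-month or 7-month dorsal library, 6 without the 7-month flank library, 13 without the 8-month snout or flank library) to 42 without the 7-month volar library (40 without the 4-month flank library). The second-set upper-quartile median shift was 0.12. In the second set 14 of 16 named genes kept their call, and CPHL1 (limma-voom, adjusted p = 0.198) and PHEROC (6 removals, 0.181) lost theirs. Of 18 genes called in both sets 16 had opposite signs (r = -0.23).

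Position genes of the fixed list give the same 2 readings. EN1 was higher in volar than in snout in the first set (log2 fold change 4.47, adjusted p = 0.00121; 0.0565 without the 7-month pig) and lower in snout than in flank in the second (-3.74 ± 0.47, 0.00113). LMX1B was higher in snout than in flank in both sets (3.21 ± 0.29 and 0.99 ± 0.22). The second-set call was lost without the 6-month snout library (adjusted p = 0.0735) or the 5-month flank library (0.0542). It was lower in first-set volar than dorsal (-1.54; 0.00294, and 0.0533 without the 7-month pig) but higher in second-set volar than flank (2.54 ± 0.23, 0.00047) and dorsal (1.86 ± 0.22, 0.00293). HOXC10 was higher in volar than in flank in the first set (1.47; adjusted p = 0.0265), a call lost without the flank (0.0664) or volar (0.0794) library of the 4-month pig or the flank (0.0523) or volar (0.0586) library of the 7-month pig. TBX4 was higher in first-set volar than snout (2.67; 0.0121, with 0.0517 without the 7-month snout library and 0.181 without that pig). DKK1 passed only for snout minus flank in the second set (2.07; 0.0315), and not once any of its 8 libraries was removed (adjusted p 0.0506 to 0.198). Summed HOX paralogs 9 to 13 reached 47.4, 25.5, 57.2 and 4.75 CPM in volar, flank, dorsal and snout of the first set and 5.5, 39.1, 29.5 and 61 CPM in the second. KRT9, PITX1, HOXA13 and HOXD13 had no matched identifier and are not analysed here.

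Genes that differ between 1 site and each of the other 3 name what is particular to a label. In first-set volar, AQP2, S100A8, RHCG, ARG1, MMP13, S100A12, AQP5 and EPHA8 stood highest above the rest, and hair genes such as KRT71, TCHHL1, VSIG8 and KRT39 lay furthest below. KRT24, TMPRSS11D and the craniofacial list genes PAX7 (0.555 CPM) and ALX1 marked first-set snout, which lacked HOXC9, HOXC8, HOXC4 and TBX5. Second-set flank carried AQP2, AQP5, ARG1, RHCG, SPINK9 and KRT1 and lacked KRT85, KRTAP24-1, TCHHL1 and LGR5, and second-set volar carried MYOT, KRT24 and MYL11 and lacked HOXC4, HOXC9 and TBX5. In all, 4649 genes of the first set and 6794 of the second differed in any site. The first set had 1122 genes set apart in volar (640 higher, 482 lower), 11 in flank (7 higher, 4 lower), 2 in dorsal (1 higher, 1 lower) and 231 in snout (171 higher, 60 lower). The second had 472 in volar (369 higher, 103 lower), 4300 in flank (2043 higher, 2257 lower), 3 in dorsal (1 higher, 2 lower) and 2 in snout (2 higher, 0 lower). Independent lists would share 20.7 and 14.5 genes (higher, lower) for first-set volar and 117 and 183 for second-set flank. The 3 comparisons of a site share its libraries, which raises their overlap, so the excess over these numbers is not read as an effect. With the pig as block, first-set flank had 22, second-set dorsal 25 and second-set snout 4. First-set volar fell to 719, 692 or 634 without the 8-month snout, 7-month snout or 7-month volar library, and first-set snout to 140 or 142 without the 4-month or 7-month dorsal library. First-set flank ran from 0 to 27 and dorsal from 0 to 3 over all removals. Second-set volar ran from 208 to 233 without a volar or snout library, flank fell to 2847 without the 5-month volar library, dorsal ran from 0 to 7 and snout from 0 to 1. Scaling by median ratios or upper quartile left 1 gene (1 higher, 0 lower) in first-set dorsal, and upper quartile gave 2 higher and 2 lower in second-set dorsal. Upper quartile also turned the first-set volar split to 521 higher and 572 lower.

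Interaction tests put a size on the disagreement between sets. EN1 and SP8 were called in opposite directions in the 2 sets for volar minus flank, as were KRT1 and AQP5. Of 15735 genes in the joint fit, 7726 (49.1%) had a volar minus flank difference that was not the same in the 2 sets, 6822 (43.4%) for snout minus flank and 6140 (39%) for dorsal minus flank. Volar minus snout had 1712 (10.9%), volar minus dorsal 583 (3.7%) and snout minus dorsal 386 (2.5%). For snout minus dorsal the log2 fold changes of the sets had r = -0.09, and the second set called 6 genes. Of 3 genes called in both sets for this pair 2 had opposite signs, so its small interaction count is not read as agreement. Only 7.4% of genes had the same volar minus flank direction in all 5 pigs, near the 6.25% of coin tosses, and 37.4% did so for volar minus dorsal. Pigs of the same set were alike, so the 5 directions are not independent. A share near 6.25% therefore does not mean that directions were random.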

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

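All the explanations below were tested only after the result was seen. The first observation is that the difference between sites depended on the library set. EN1, KRT1 and AQP5 peaked under volar in the first set and under flank in the second, and ALX1 and KRT24 under snout and under volar. Tested as an interaction, 7726 genes had a volar minus flank difference that was not the same in the 2 sets, 583 a volar minus dorsal, 1712 a volar minus snout, 6822 a snout minus flank, 386 a snout minus dorsal and 6140 a dorsal minus flank difference.

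A shift between library sets, the age of the pigs, the date of harvest and the site names were tested as explanations. A shift between library sets that is alike at every site would leave the site differences in place, but the volar minus flank log2 fold changes of the sets ran against each other (r = -0.58 across genes). A trend with age would put the pig of 5 months next to the pig of 4 months. Their volar minus flank profiles had r = -0.48 across the 2000 most variable genes, which the r values below use as well. The sites of a pig share 1 date of harvest, so a date effect alike at every site would cancel in these profiles, but the highest r of a second-set pig with the 4-month or 8-month pig was -0.45. Those 2 pigs also differ in date and had 0.77. Volar minus dorsal went the other way, with 0.55 to 0.56 between second-set pigs and those 2 pigs, and 0.89 between those 2 pigs. The remaining pairs of sites ran from -0.56 to 0.13 between second-set pigs and those 2 pigs. An effect of date that differs between sites was not tested. With the second set's names reassigned to the first set's site profiles, the best of the 24 assignments reached a mean r of 0.88, against -0.11 with the names as deposited, which ranked 19 of 24. Skeletal muscle genes were not left out of these scores. The second-best reached 0.79 and left dorsal under its own name, with snout matching flank. Summed HOX paralogs 1 to 8 argue against that one: they were 98.2 ± 4 CPM (mean ± SD) in flank and 48.5 ± 11 CPM in dorsal of the first set, and 97 ± 3.9 CPM under dorsal and 51.8 ± 8.3 CPM under snout in the second. Site names out of place in 1 library set are therefore a candidate explanation, found and tested on the same data, and no library was moved on its account.

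HOX genes bear on which set that may be. Patterning of the head does without HOX paralogs 9 to 13. The libraries named snout had a summed 4.75 CPM of them in the first set, which argues against another site under that name there. An exchange of names among first-set volar, flank and dorsal would leave this value as it is, so the value does not bear on it. In the second set the libraries named snout had 61 CPM of these paralogs, more than any other label of that set, and those named volar 5.5 CPM. The list includes HOXC13, which is also in the list of hair follicle regulators, so these sums are not of position alone. These values are in line with names out of place in the second set. Another depth or place of sampling on the snout would leave craniofacial genes high there. Their summed level was 143 ± 4.9 CPM (mean ± SD) under snout in the second set, below 239 ± 28 CPM in the first and 252 CPM under second-set volar, which argues against it. Second-set flank was at 185 ± 12 CPM. The craniofacial list shares DLX3 with the hair follicle regulators and PAX9 with mucosal epithelium, so these sums are not of position alone either.

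Skeletal muscle genes stood out in 3 libraries. Their summed level was 11200 CPM in the snout library of the 7-month pig, against 42.6 to 55.2 CPM in the other 4 snout libraries, and 8800 and 5500 CPM in the second-set volar libraries of the 6-month and 5-month pigs. In each of these 3 libraries 19 of the 20 members were at least 10 times the median of the other 17 libraries, as muscle fibres in the biopsy would give. The 3 libraries were picked by the sum of this same list, so the count is not an independent test. It shows that the rise was found in most members, and does not show how the sum was shared among them. The most abundant were NEB (1850, 2040 and 1010 CPM), ACTA1 (2240, 1220 and 751 CPM), CKM (1220, 1050 and 600 CPM) and MYBPC1 (1090, 755 and 594 CPM), with medians of 1.13, 0.704, 2.43 and 1.2 CPM elsewhere. None of the members is in another list (0 of 20), and 8 had a median of at least 1 CPM in the other libraries. Muscle in a 4 mm punch may account for these 3 libraries and was not tested apart from this list.

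Single values lay far from the other 4 pigs of their label in 6 of 83 groups of 5 tested, where chance gives about 1 in 20. EN1 in the dorsal library of the 5-month pig was 3.36 CPM (others 0.728 to 1.38), TBX4 in its snout library 4.21 CPM (0.334 to 1.27), HOXA9 in its flank library 24.4 CPM (1.28 to 7.39) and in its snout library 23.6 CPM (0 to 5.18). The summed HOX paralogs 9 to 13 of its flank library were 50.1 CPM (22.2 to 28.1), and the summed muscle genes are given above. The 5-month pig belongs to the second set, and these groups mix the sets.

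Other splits of the same samples were counted for each result. With all libraries in 1 fit the real split called 0 genes in each of 11 results, so 100 of 100 splits gave as many by construction, which says nothing about chance. The highest other counts were 2722 for volar and flank, 0 for volar and dorsal, 350 for volar and snout, 678 for snout and flank, 1 for snout and dorsal, 343 for dorsal and flank and 2434 for any site, and 953, 0, 54 and 43 for genes set apart in volar, flank, dorsal and snout. Splits that call up to 2722 genes where the real one calls 0 point to a structure of the samples that the labels do not follow. Of the 12 splits that part all 5 pigs, the highest counts were 1062 for volar and flank, 69 for volar and snout and 1 for snout and flank, with 0 in the other 3 comparisons. Within the first set 3 libraries against 3 make 10 splits, too few for a share under 0.05: the real counts of 5032, 3694, 1768, 2024, 1212 and 20 compare with highest others of 1, 0, 0, 2, 0 and 0, and 1 of 10 splits, the real one, gave as many in each. For any site 1 of 100 splits gave 4649 (highest other 518), and for genes set apart in volar 1 of 100 gave 1122 (11). In flank 2 of 100 gave 11 (24), in dorsal 2 of 100 gave 2 (24) and in snout 2 of 100 gave 231 (559). These shares are under 0.05, but most of the splits mix libraries of a pig within a site. Only 6 of the 100, the real one included, part all pigs as the real one does, with 0 genes in the other 5 for each of these results, too few for a share under 0.05. The second set has 2 pigs, and splits of it were not counted.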

How the results depend on the processing

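Alternatives within a set and for its lists were chosen after seeing the data, and the others before. With all libraries in 1 fit the count of 0 held in each of the 11 results under the pig as block, both scalings, limma-voom, the other count filters, a log2 fold change of at least 1 (not run for any site), a non-robust spread and the 20 most abundant genes left out. It did not hold in DESeq2 (319 for volar and flank, 1631 volar and dorsal, 47 volar and snout, 304 snout and flank, 70 snout and dorsal, 186 dorsal and flank, 781 any site, and 19, 10, 7 and 1 set apart in volar, flank, dorsal and snout). With only the 2 sites in the fit it was 2595 for volar and dorsal and 1 for dorsal and flank. In the first library set alone the counts were 5032, 3694, 1768, 2024, 1212, 20 and 4649 in that order, and 1122, 11, 2 and 231 set apart. In the second they were 5884, 1981, 1551, 6559, 6, 7140 and 6794, and 472, 4300, 3 and 2. The cause of the change within sets is taken up with the label disagreement, and that of the DESeq2 counts was not tested. Leaving out each pig or library gave 0 to 5 for volar and flank, 0 to 3 for volar and dorsal, 0 to 0 for volar and snout, 0 to 2 for snout and flank, 0 to 0 for snout and dorsal, 0 to 0 for dorsal and flank, 0 to 30 for any site, 0 to 0 for set apart in volar, 0 to 0 for set apart in flank, 0 to 0 for set apart in dorsal and 0 to 0 for set apart in snout.

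Within sets, most alternatives kept a count within 1.5 times. In the first set DESeq2 gave 2730 for volar and snout, 3038 snout and flank, 2045 snout and dorsal, 350 dorsal and flank, and 1763, 214, 28 and 357 set apart in volar, flank, dorsal and snout, limma-voom 48 for dorsal and flank and 29 set apart in flank, and the pig as block 32 and 22. Both scalings and leaving out the 20 most abundant genes gave 1 set apart in dorsal. A log2 fold change of at least 1 left 2680 for volar and flank, 1904 volar and dorsal, 1104 volar and snout, 1212 snout and flank, and 603 and 1 set apart in volar and dorsal, by its own construction. In the second set DESeq2 gave 3017 for volar and dorsal, 2469 volar and snout, 272 snout and dorsal, and 149 and 34 set apart in dorsal and snout. The block gave 34 for snout and dorsal, and 25 and 4 set apart in dorsal and snout, no count filter 6 set apart in dorsal, and a log2 fold change of at least 1 left 3744 for volar and flank, 4275 snout and flank and 2587 set apart in flank. The block moved no other count of genes or lists by over 1.5 times. On simulated data DESeq2 made 62 false calls in the first set, 40 in the second and 21 with all libraries, against 7, 5 and 3 in edgeR, for volar minus flank. The cause of the other changes was not tested.

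Removing each pig or library of the first set gave 2424 to 5035 for volar and flank, 1303 to 4051 for volar and dorsal, 269 to 2009 for volar and snout, 501 to 2136 for snout and flank, 271 to 1370 for snout and dorsal, 0 to 42 for dorsal and flank, 1659 to 4588 for any site, 161 to 1191 for set apart in volar, 0 to 27 for set apart in flank, 0 to 3 for set apart in dorsal and 48 to 228 for set apart in snout. Removing each library of the second set, where the lone library of a site is assumed to vary like the others, gave 3554 to 6046 for volar and flank, 693 to 1903 for volar and dorsal, 464 to 1651 for volar and snout, 4023 to 6634 for snout and flank, 0 to 8 for snout and dorsal, 5469 to 6749 for dorsal and flank, 4872 to 6733 for any site, 208 to 438 for set apart in volar, 2847 to 4211 for set apart in flank, 0 to 7 for set apart in dorsal and 0 to 1 for set apart in snout. Removing a pig of the second set leaves no residual degrees of freedom. The count of genes set apart in volar fell to 634 in the first set without the 7-month volar library. Fewer libraries are part of the cause by construction.

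Of the genes named in any case, some change sign between the pooled fit and a set alone. In the first set alone EN1 was 3.72 and HOXC10 1.47 for volar minus flank, LMX1B -1.54 for volar minus dorsal and TBX5 8.88 for volar minus snout. In the second alone EN1 was -1.89 and HOXC10 -9.14 for volar minus dorsal, LMX1B 1.55 and HOXC10 -9.78 for volar minus snout and TBX5 2.06 for snout minus flank. HOXC10 had no count in second-set volar and TBX5 a single count in first-set snout, so the sizes of -9.14, -9.78 and 8.88 depend on the prior count added by the fit and only their direction is to be read.

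Lists called by camera with a preset correlation were mostly lost with an estimated one. In the pooled fit an estimated correlation left 0 in each comparison, and fry 0 for dorsal and flank, 0 snout and dorsal, 3 snout and flank, 1 volar and dorsal, 1 volar and flank and 0 volar and snout. In the first set it left 4 for dorsal and flank (fry 5), 2 snout and dorsal, 4 snout and flank, 0 volar and dorsal, 1 volar and flank and 2 volar and snout. In the second it left 0 in each, and fry 1 for snout and dorsal.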

Other observations

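Nerve, gland and matrix genes add to the first-set contrasts. Schwann cell genes were lower in volar than in flank, with 0 higher and 6 lower of 16 (camera adjusted p = 0.0116, or 0.493 with an estimated correlation, and 0 and 7 over the list alone), EGR2 among them (log2 fold change -4.56 ± 0.58). EGR2 is also in the immediate early and heat shock list. Summed, the Schwann cell list was at 387 ± 75 CPM (mean ± SD) in volar and 414 ± 110 CPM in flank, a difference within the spread of the libraries. Sebaceous gland genes had 3 higher and 13 lower of 23 (0.0123, or 0.555 with an estimated correlation, and 3 and 16 over the list alone), with ALOX15B at -3.75 ± 0.60. Their summed level was 1840 ± 270 CPM (mean ± SD) in volar and 5950 ± 7600 CPM in flank, so it varied widely between flank libraries. BMP3 (-4.91 ± 0.33) and WNT16 (-4.05 ± 0.26) were lower in volar as well. Genes of elastic fibres, proteoglycans and matrix enzymes had 3 higher and 19 lower of 39 (0.000166, or 0.555 with an estimated correlation, and 4 and 25 over the list alone), with POSTN at -3.29 ± 0.18. MITF, a regulator of melanocytes, was lower in volar than in dorsal (-1.40 ± 0.14), where 3 of 9 melanocyte genes fell and 0 rose (0.0173, or 0.329 with an estimated correlation).

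The test below was chosen only after the label disagreement was seen. Profiles of volar minus flank in the 7-month and 8-month pigs had r = 0.82 and 0.77 across the 2000 most variable genes with that of the 4-month pig, and the 6-month pig -0.45. Dorsal minus flank was less alike among the first-set pigs (r = 0.25, 0.29 and 0.39), and the 7-month flank library was closest to dorsal. The 2 pigs of the second set gave the same matches, with flank libraries at r = 0.87 and 0.87 to first-set volar. If names are out of place, the same exchange may therefore have happened in both pigs of the second set, which the mean r of 0.88 over all 4 names covers. Whether it arose at sampling, library preparation or deposit cannot be read from counts.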
